A study of Homo sapiens with 22 samples.

How the data were processed

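RNA was measured in 22 libraries of 11 sorted human cell populations, 10 from thymus and 1 from cord blood. Per the labels, RNA was extracted with the miRNeasy Mini Kit, libraries were made with the TruSeq Stranded mRNA kit, and single reads of 75 bases were sequenced on a NextSeq instrument. Per the submitters' processing notes, reads were aligned with STAR to GRCh38 and counts were processed with DESeq2. The deposited table used here holds raw integer counts per gene and library, per the file headers and a check that its values were whole numbers. The program that counted the reads, its strand setting and the annotation release are not given in the sources used here. A second deposited table of normalized counts, written with decimal commas, was not used here.

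The count table had 40037 genes, of which 38782 IDs were found in GENCODE release 44, which gave symbols and gene types. Positions are those of the deposited table. A total of 77 genes on the Y chromosome or of X inactivation were left out, which left 39960. Library totals ranged from 25135294 counts in HPC replicate 2 to 46114834 counts, and the next lowest was 34094731. A count of 0 was read as up to 3 counts over the group, and such floors cover counting error only. Of 202 named genes and sort markers, 44 overlap another gene on the same strand and 91 on the opposite strand, 107 in either way. Since the counting is not described, values of overlapping genes (among them RAG1 and RAG2, HOXA neighbours, KLRK1, ETV5, CD27, DSCAML1, TCF7, FOXP3, ZBTB7B and CD52) are uncertain, as are those of near-identical copies such as TCR segments, HLA genes, alpha globins and XCL1 with XCL2.

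Counts were scaled by TMM and fitted with edgeR 4.0.16 (R 4.3.3, limma 3.58.1) in one model of 11 groups over all 22 libraries, after filterByExpr had kept 24961 genes. A gene was called changed with a robust quasi-likelihood test at a Benjamini-Hochberg adjusted p under 0.05 within its comparison and an absolute log2 fold change of at least 1. Each adjusted p of a gene in the report is from this edgeR test. Standard errors were computed from the fold change and the test statistic. Consecutive stages were compared, as were SP CD4+ with SP CD8+ cells, the mean of both SP groups with DP CD3+ cells, the gamma delta groups with each other and their mean with that of the SP groups. An interaction compared the maturation step of gamma delta cells with that of alpha beta cells. A test across all groups required an adjusted p under 0.05 and a range of group means of at least 2 on the log2 scale. Where a list is discussed, "rose" and "fell" mean that it passed its test.

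Lists of genes for stages, lineages, functions and other cell types, 31 in all, were fixed before the data were examined, as were the design, the alternatives and the genes to be named. The mitochondrially encoded genes had no rows analysed, so 30 lists were tested in 11 comparisons, 330 tests. Lists were tested with camera at a preset correlation between genes of 0.01 and Benjamini-Hochberg adjustment over all 330 tests, and again with the correlation estimated from the data. Of 151 list calls, 36 held with an estimated correlation, and for the others the report gives the second p value beside the call, so a list call printed with 1 p value holds with an estimated correlation. Counts "adjusted over the list alone" adjusted the p values of the members of 1 list. The genes named were, in each comparison, the 6 largest increases and 6 largest decreases among protein-coding genes past the threshold with at least 20 CPM in every library of the higher side and no overlap between the libraries of the sides. To these came up to 3 members in each direction of each list assigned to the comparison, or up to 2 members with the highest CPM where none passed, and the 14 sort markers. For the interaction, up to 4 genes were named that passed in both steps in opposite directions. Markers of other cell types that are given per library (PAX5, IRF8, MPO, LYZ, CSF1R) and the genes of the last part were chosen after their values were seen. Some genes that met these rules are not reported here, and the lists and the counts of named calls include them.

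The alternatives were RLE scaling, no filter on low counts, DESeq2 1.42.0, no fold change threshold, the replicate number as a block, only the groups compared, and each library left out in turn. Chosen after seeing the data were fits without HPC, with a block over the 20 thymus libraries, and without replicate 2 of both SP groups. The labels number the replicates 1 and 2 in each population. For 45 pairs of thymus groups, deviations from the group mean correlated between equal numbers by 0.137 to 0.547 (median 0.380), so the numbers were taken to pair the thymus samples. With HPC the correlations were 0.000309 to 0.107 over 10 pairs.

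The scripts were tested on simulated data of the comparison of CD34+ CD1+ with CD34+ CD1- cells, with 24092 genes fitted. Of 100 genes changed 2-fold edgeR called 13 and DESeq2 31, and of 100 changed 4-fold they called 78 and 92. Unchanged genes were called 2 times by edgeR and 40 times by DESeq2. A list of 40 genes raised 2-fold was called and 0 of 20 random lists were. The simulated genes and libraries varied independently, without correlation between genes or pairing of replicates. The random lists therefore do not measure how often lists are falsely called in the real data. Tables and figures were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.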

Results

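RNA was sequenced from 11 sorted human cell populations, 2 libraries each. 10 populations came from thymus and covered T cell development from CD34+ progenitors to mature alpha beta and gamma delta T cells. The other, haematopoietic progenitor cells (HPC), was CD34+ cord blood cells lacking CD3, CD14 and CD56. Early thymocytes were sorted as CD34+ CD1-, CD34+ CD1+ and CD34+ CD4+ cells, followed by CD4+ CD28+ immature single-positive cells (ISP) sorted without CD3 and CD8. CD4+ CD8+ (DP) cells were taken without and with CD3, and single-positive (SP) CD4+ and CD8+ cells with CD3. Gamma delta cells carried CD3 and the gamma delta T cell receptor (TCR) and were divided by CD1. Library totals were 25135294 to 46114834 counts. Levels are in CPM after TMM scaling, given as mean ± SD over the libraries of a group, n = 2 unless stated, and log2 fold changes as estimate ± SE. The labels call the libraries of a group biological replicates but do not state donor or thymus, so p values measure only the spread between these samples.

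CD34, CD4 and CD8A transcripts were highest in populations sorted for these proteins, while CD3 chain and CD8A transcripts were also present in ISP cells, which were sorted without them. CD34 (ENSG00000174059, GRCh38 chromosome 1, 207880972 to 207911402) was at 728 ± 0.116 CPM in HPC, 409 ± 59.7 CPM in CD34+ CD1- cells, 163 ± 78.3 CPM in CD34+ CD1+ cells and 40.8 ± 9.42 CPM in CD34+ CD4+ cells. In the later thymic groups CD34 was at most 1.36 CPM. CD1A, which marks T-lineage-committed thymocytes, was at 27.3 ± 20.8 CPM in CD34+ CD1- cells and 1481 ± 173 CPM in DP CD3- cells. CD8A (ENSG00000153563, GRCh38 chromosome 2, 86784610 to 86808396) reached 2252 ± 155 CPM in DP CD3- and 1641 ± 54.8 CPM in SP CD8+ cells, against 169.9 ± 179 CPM in SP CD4+ cells. CD4 was at 697 ± 64.6 CPM in SP CD4+ and 47.8 ± 61.7 CPM in SP CD8+ cells. CD28 was at 99.6 ± 8.61 CPM in ISP and highest in SP CD4+ cells at 519.7 ± 18.2 CPM. The CD3 chain genes were expressed before surface CD3, with CD3E at 509 ± 114 CPM in CD34+ CD1- cells, CD3D at 371 ± 72.3 CPM and CD3G at 251 ± 18.5 CPM in CD34+ CD4+ cells. TRDC, the TCR delta constant segment (ENSG00000211829, GRCh38 chromosome 14, 22272262 to 22465787), was at 1001 ± 159 CPM and 1276 ± 43.2 CPM in the gamma delta groups, and at 324 ± 26.1 CPM in ISP. TRAC, the alpha constant segment (ENSG00000277734, GRCh38 chromosome 14, 22203093 to 22552155), was at 361 ± 25.9 CPM in DP CD3- and 1466 ± 393 CPM in DP CD3+ cells. TRBC1 was at 2094 ± 514 CPM in DP CD3+ cells. TRGC1 was at 216 ± 47.1 CPM in gamma delta cells titled CD1- and 141 ± 3.425 CPM in those titled CD1+. The deposited position of TRAC overlaps TRDC on the same strand, and TRBC1 and TRGC1 have near-identical copies, so these levels are uncertain.

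The gamma delta libraries titled CD1- held 4.27 ± 3.40 CPM of CD1A and 5.08 ± 4.70 CPM of CD1B, against 491 ± 182 CPM and 312 ± 130.2 CPM in those titled CD1+. The sort phenotype entries give these populations the opposite CD1 sign from their titles. The titles are used here as names, and every direction below refers to the libraries so titled.

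**Figure D1:**
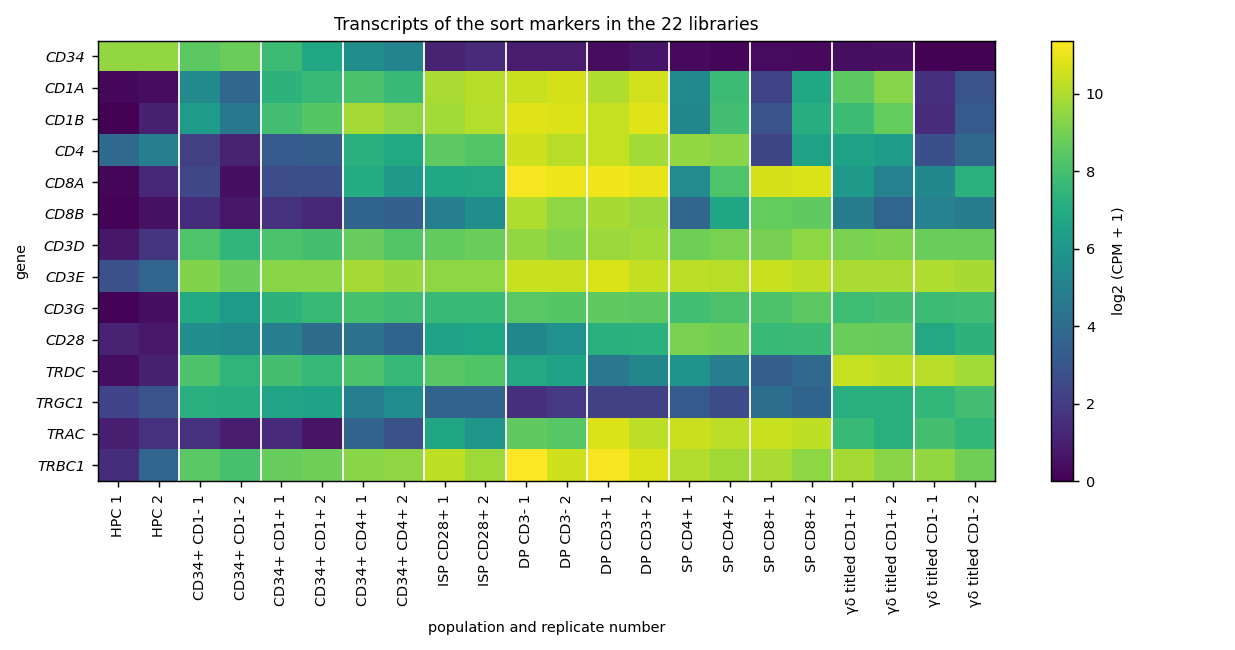
Transcript levels of the 14 sort marker genes as log2(CPM + 1) (colour) in each of the 22 libraries (columns), ordered by population. CD34 falls from HPC to CD34+ CD4+ cells, and the CD1 genes are low in both gamma delta libraries titled CD1-.

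Across the 11 populations, 8700 of 24961 genes differed with a range of group means of at least 2 on the log2 scale. The number of these genes with their highest mean in a given population was 2367 in HPC, 1119 in gamma delta cells titled CD1-, 1098 in ISP and 703 in DP CD3+ cells. SP CD4+ and SP CD8+ cells held 664 and 635 such genes, DP CD3- cells 551, and CD34+ CD4+, CD34+ CD1- and CD34+ CD1+ cells 535, 492 and 273. Gamma delta cells titled CD1+ held 263.

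**Figure D2:**
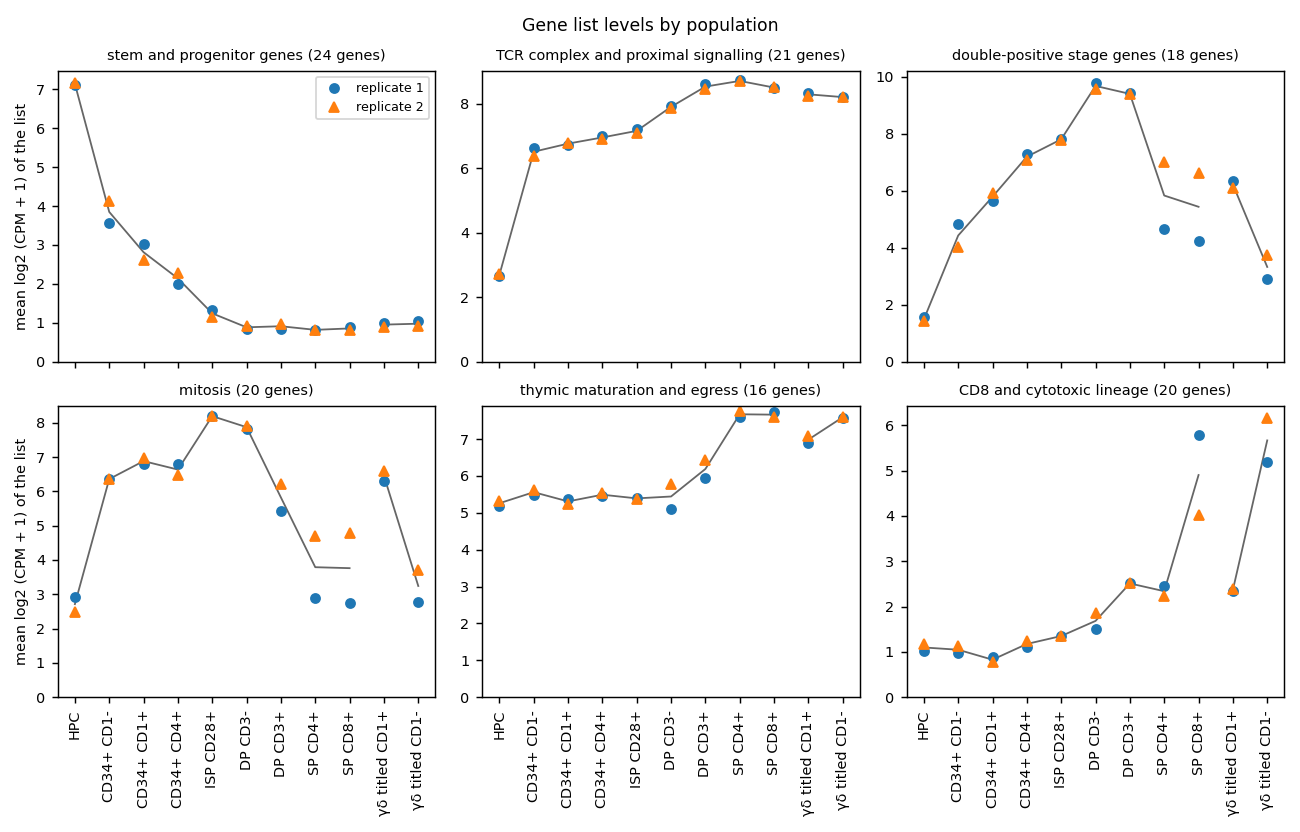
Mean log2(CPM + 1) of the members of 6 gene lists (vertical axes) by population (horizontal axes), with a point per library, 2 per population. The mitosis list is highest from ISP to DP CD3- cells, and the list of double-positive stage genes peaks in the DP populations.

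**Figure D3:**
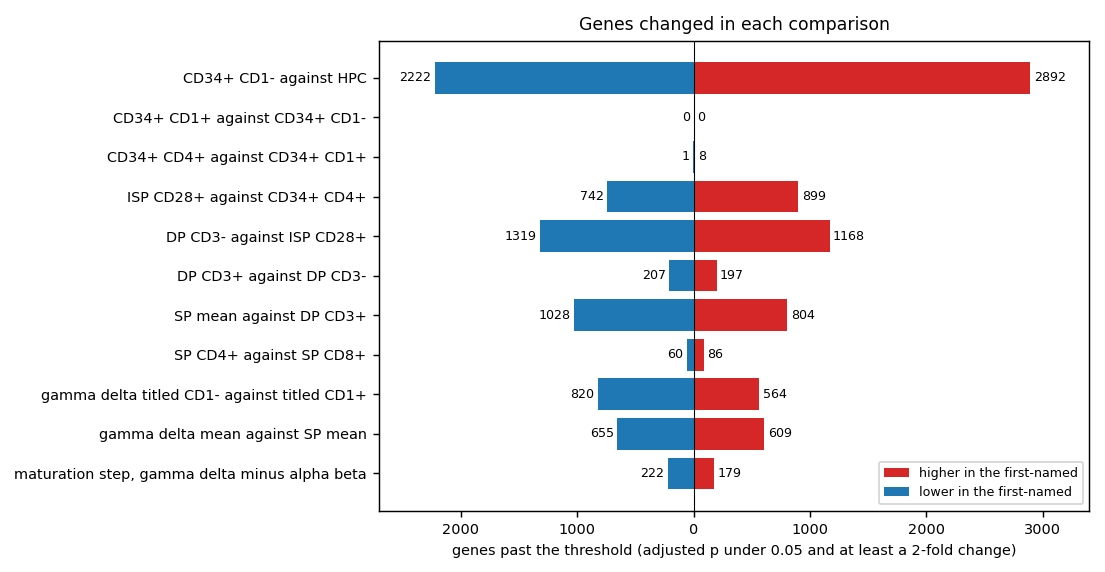
Number of genes higher (bars to the right) and lower (bars to the left) in each of the 11 comparisons at an adjusted p under 0.05 and an absolute log2 fold change of at least 1. The comparison of CD34+ CD1+ with CD34+ CD1- thymocytes has 0 genes and that of CD34+ CD1- thymocytes with HPC has 5114.

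From HPC to CD34+ CD1- thymocytes, genes of the TCR complex rose (adjusted p = 1.23e-68) and stem and progenitor genes fell (adjusted p = 1.16e-08), each as a list. BCL11B, a transcription factor required for T-lineage commitment (ENSG00000127152, GRCh38 chromosome 14, 99169287 to 99271524), was at 238 ± 45.0 against 0.542 ± 0.433 CPM (log2 fold change 8.88 ± 0.41, adjusted p = 4.01e-09). TAL1, a regulator of stem cells and erythroid cells (ENSG00000162367, GRCh38 chromosome 1, 47216290 to 47232220), was at 0.116 ± 0.165 against 118 ± 8.01 CPM (log2 fold change -9.95 ± 1.57, adjusted p = 0.000254). This comparison addressed the first steps into the T lineage, with tissue and stage changing together. Among the largest increases were STRA6, the receptor for retinol-binding protein, from 0.0590 ± 0.0834 to 45.2 ± 1.81 CPM and DPP4, a T cell surface peptidase, from 0.0885 ± 0.125 to 62.9 ± 17.6 CPM. CD3G, a CD3 chain, rose by 8.90 ± 0.41 on the log2 scale, CAMK4, a calcium-dependent kinase, by 8.89 ± 0.29 and ICOS, a costimulatory receptor, by 8.87 ± 0.44. Among the decreases, AVP, a peptide hormone gene used as a marker of primitive stem cells, had 0 counts in the thymic libraries against 78.0 CPM in HPC, at least 2000.5-fold lower at a floor of 3 counts over the group. AVP and MYCT1, a MYC target (log2 fold change -9.79 ± 1.06), were past the threshold in edgeR and not in DESeq2. AREG, an epidermal growth factor receptor ligand, changed by -9.74 ± 1.37 and HBB, the beta globin gene, by -9.58 ± 1.63, while HBA2, an alpha globin gene with a near-identical copy, was at 0.0259 CPM against 41.1 CPM in HPC.

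The TCR complex and its signalling genes rose as a list, with 18 of 21 members higher, none lower and 3 not past the test (18 adjusted over the list alone; adjusted p = 1.23e-68). CD2, an adhesion receptor of T cells, changed by 7.63 ± 0.49, and THEMIS, a TCR signalling adaptor, was at 16.9 CPM against 0.0707 CPM. Of 15 T-lineage transcription factors 8 rose and 7 did not pass (8 adjusted over the list alone; adjusted p = 4.07e-12). TCF7 changed by 6.68 ± 0.42 and LEF1 by 4.60 ± 0.29, both effectors of WNT signalling. The Notch target list rose with 7 of 11 members (7 adjusted over the list alone; adjusted p = 9.13e-07). PTCRA, the pre-TCR alpha chain, changed by 8.12 ± 1.19, IL7R, the IL7 receptor, by 7.53 ± 0.35 and NOTCH3, a Notch receptor, by 4.99 ± 0.87. All 20 mitosis genes rose (20 adjusted over the list alone; adjusted p = 1.07e-12, adjusted p = 0.254 with an estimated correlation). TOP2A, a topoisomerase, changed by 6.02 ± 0.93, KIF20A, a mitotic kinesin, by 5.04 ± 0.77 and MKI67, a proliferation marker, by 4.74 ± 1.03.

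Stem and progenitor genes fell as a list, with 15 of 24 members lower, none higher and 9 not past the test (16 adjusted over the list alone; adjusted p = 1.16e-08). MECOM, a stem cell transcription factor, changed by -7.62 ± 1.07. MHC class II genes fell in 9 of 10 members (10 adjusted over the list alone; adjusted p = 8.70e-07, adjusted p = 0.159 with an estimated correlation). HLA-DQB1 changed by -5.16 ± 1.02, HLA-DQA1 by -4.38 ± 1.17 and HLA-DPB1 by -4.19 ± 0.79, each with similar relatives that make the split of reads uncertain. The HOXA cluster fell with 4 of 9 members lower, 1 higher and 4 not past the test (1 higher and 5 lower adjusted over the list alone; adjusted p = 0.0145, adjusted p = 0.0929 with an estimated correlation). HOXA5 changed by -2.93 ± 0.45, HOXA3 by -2.60 ± 0.56 and HOXA2 by -4.27 ± 1.41, while HOXA7 went the other way at 2.53 ± 0.79. Of 5 neutrophil granule genes 1 fell, AZU1 (-6.04 ± 1.76), and the list did not pass (adjusted p = 0.298). Markers of erythroid cells and megakaryocytes fell in 9 of 11 members beside them (11 adjusted over the list alone; adjusted p = 9.80e-06, adjusted p = 0.0989 with an estimated correlation). In total 2892 genes rose and 2222 fell, against 2492 and 2615 with RLE scaling, which shifted the log2 fold changes by a median of -0.14, and 2880 and 3184 with DESeq2, so which direction had more genes depended on the method. A fit of only these 4 libraries gave 1304 genes. The 2 HPC libraries correlated at 0.915 in log2 CPM, against 0.973 for the CD34+ CD1- libraries. Of 31 named gene calls, 28 and 25 held without CD34+ CD1- replicate 1 and 2, and 30 and 28 without HPC replicate 1 and 2.

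CD34+ CD1+ thymocytes, the next stage sorted, had no gene past the edgeR test against CD34+ CD1- cells without a block, where 871 genes had an unadjusted p under 0.05 and DESeq2 gave 67, while several gene lists moved. CD34 was at 163 ± 78.3 against 409 ± 59.7 CPM, a log2 fold change of -1.33 ± 0.31 that did not pass (adjusted p = 0.358). IRF8, a transcription factor of dendritic cells, was at 14.4 ± 2.22 against 115 ± 103 CPM and did not pass either (-3.00 ± 0.66, adjusted p = 0.293). The comparison addressed what accompanies the gain of CD1 and T-lineage commitment. Stem and progenitor genes fell as a list of 24 with none past the test singly (4 lower adjusted over the list alone; adjusted p = 2.61e-13), and ERG, an ETS factor of stem cells, was at 113 ± 15.6 against 171 ± 1.30 CPM. The TCR complex list of 21 rose (1 lower adjusted over the list alone; adjusted p = 6.41e-06). CD3E was at 643 ± 1.74 against 509 ± 114 CPM and ZAP70, the TCR-proximal kinase, at 604 ± 74.5 against 544 ± 31.8 CPM. T-lineage transcription factors rose as a list of 15 (1 lower adjusted over the list alone; adjusted p = 0.000304, adjusted p = 0.0950 with an estimated correlation). TCF7 was at 1919 ± 56.8 against 1249 ± 461 CPM and MYB, a progenitor transcription factor, at 600.1 ± 51.1 against 549.7 ± 39.9 CPM. MHC class II genes fell as a list of 10 (1 lower adjusted over the list alone; adjusted p = 1.04e-09, adjusted p = 0.0950 with an estimated correlation). CD74, the invariant chain, was at 127 ± 34.9 against 455 ± 260.4 CPM and HLA-DRA at 44.4 ± 1.22 against 152 ± 91.8 CPM.

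Plasmacytoid dendritic cell markers fell as a list of 10 (4 lower adjusted over the list alone; adjusted p = 1.91e-07, adjusted p = 0.0810 with an estimated correlation), although PTCRA, a member that thymocytes also use, was at 392 ± 39.1 against 138 ± 65.2 CPM. B cell markers fell in the same comparison as a list of 11 (5 lower adjusted over the list alone; adjusted p = 4.75e-11, adjusted p = 0.0516 with an estimated correlation). NK cell markers fell as a list of 12 (3 lower adjusted over the list alone; adjusted p = 0.00191, adjusted p = 0.167 with an estimated correlation), but not without CD34+ CD1+ replicate 2 (adjusted p = 0.226). The 2 CD34+ CD1- libraries were unequal in such markers, with PAX5, a B cell factor, at 0.362 and 16.3 CPM, IRF8 at 42.6 and 188 CPM and MPO, a granule enzyme, at 63.1 and 268 CPM in replicate 1 and 2. The recombination list did not pass (adjusted p = 0.161). DNTT, the nucleotide-adding transferase, was at 1571 ± 229 against 1396 ± 299 CPM and PRKDC, the repair kinase, at 801 ± 5.63 against 757 ± 8.80 CPM. Monocyte and dendritic cell markers, HOXA genes and Notch targets did not pass (adjusted p = 0.991, 0.890 and 0.812), and their medians, means and tests differed in sign. Of the myeloid markers, CD1C was at 58.5 ± 17.9 against 9.93 ± 5.45 CPM and LYZ, lysozyme, at 4.03 ± 0.878 against 10.2 ± 3.90 CPM. HOXA9 was at 17.2 ± 2.78 against 16.9 ± 1.82 CPM and HOXA10 at 12.8 ± 0.833 against 13.5 ± 0.245 CPM. NOTCH1 was at 1135 ± 18.8 against 1100.0 ± 157 CPM and IL7R at 753 ± 16.4 against 519 ± 96.5 CPM. With edgeR 0 genes passed, and 14 with the replicate number as a block over the thymus libraries only. Without the block the smallest adjusted p was 0.234, and DESeq2 gave 67 genes, 26 higher and 41 lower. Without CD34+ CD1- replicate 1 the count was 16, and without CD34+ CD1+ replicate 1 it was 2.

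The step from CD34+ CD1+ to CD34+ CD4+ cells changed 9 genes, 8 higher and 1 lower. KIAA1671, a gene of little-known function, rose from 2.79 ± 1.22 to 26.1 ± 2.12 CPM (3.22 ± 0.41, adjusted p = 0.00721). SMPD3, a neutral sphingomyelinase (ENSG00000103056, GRCh38 chromosome 16, 68358325 to 68448688), rose from 20.9 ± 1.83 to 116 ± 5.17 CPM (2.47 ± 0.36, adjusted p = 0.0265). NINL, a centrosomal protein, rose from 40.6 ± 13.6 to 192 ± 6.73 CPM (2.24 ± 0.34, adjusted p = 0.0284). CD34 was the gene that fell, from 163 ± 78.3 to 40.8 ± 9.42 CPM (-1.99 ± 0.31, adjusted p = 0.0333). The comparison addressed the first appearance of CD4 before CD34 is lost. Genes of the double-positive stage rose as a list of 18 with none past the test singly (5 adjusted over the list alone; adjusted p = 2.54e-12, adjusted p = 0.103 with an estimated correlation), and RAG1, the recombinase, was at 1170.1 ± 272 against 443 ± 295 CPM. Stem and progenitor genes fell as a list, with 1 of 24 lower (4 adjusted over the list alone; adjusted p = 1.92e-08). The TCR complex list rose with none of 21 members past the test (0 adjusted over the list alone; adjusted p = 0.0154, adjusted p = 0.183 with an estimated correlation), and CD3E was at 852 ± 90.2 against 643 ± 1.74 CPM and ZAP70 at 795 ± 21.5 against 604 ± 74.5 CPM. Without CD34+ CD1+ replicate 1 or CD34+ CD4+ replicate 1 that list did not pass (adjusted p = 0.263 and 0.143).

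Mitosis genes did not pass in CD34+ CD4+ cells (adjusted p = 0.102). MKI67 was at 771 ± 87.0 against 978 ± 21.9 CPM and TOP2A at 422 ± 115 against 501 ± 18.0 CPM. The mitosis list passed as lower without CD34+ CD4+ replicate 1 (adjusted p = 0.0234). The recombination and Notch target lists did not pass (adjusted p = 0.785 and 0.597), and the signs of their medians, means and tests differed. ADA, the adenosine deaminase gene, was at 1032 ± 60.7 against 848 ± 113 CPM and DNTT at 1539.5 ± 40.8 against 1571 ± 229 CPM. NOTCH1 was at 1232 ± 291 against 1135 ± 18.8 CPM and IL7R at 1017 ± 278 against 753 ± 16.4 CPM. Monocyte and dendritic cell markers rose beside these as a list of 13 (6 adjusted over the list alone; adjusted p = 1.14e-13). NK cell markers rose as a list of 12 (2 adjusted over the list alone; adjusted p = 9.80e-06, adjusted p = 0.0757 with an estimated correlation). Plasmacytoid dendritic cell markers rose as a list of 10 (1 adjusted over the list alone; adjusted p = 0.000341, adjusted p = 0.194 with an estimated correlation), but not without CD34+ CD4+ replicate 2 (adjusted p = 0.609). LYZ was at 14.1 and 78.1 CPM and CSF1R, the monocyte growth factor receptor, at 1.58 and 11.3 CPM in CD34+ CD4+ replicate 1 and 2. With the replicate number as a block 28 genes changed, 23 higher and 5 lower, and 72 with the block over the thymus libraries only. The count of 9 was 0 without CD34+ CD1+ replicate 1, 1 without CD34+ CD1+ replicate 2 and 5 without CD34+ CD4+ replicate 1. Of the 4 named calls, 0 and 1 held without CD34+ CD1+ replicate 1 and 2, and 1 without CD34+ CD4+ replicate 1 or 2.

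ISP cells differed from CD34+ CD4+ cells at 1641 genes. PSAT1, an enzyme of serine synthesis (ENSG00000135069, GRCh38 chromosome 9, 78297143 to 78330093), rose from 4.21 ± 0.473 to 59.2 ± 10.5 CPM (3.81 ± 0.32, adjusted p = 2.72e-05). CD34 fell from 40.8 ± 9.42 to 1.36 ± 0.346 CPM (-4.91 ± 0.37, adjusted p = 2.17e-05). This step spans the loss of CD34 and beta selection. CCNI2, a cyclin-like gene, rose by 4.47 ± 0.80, and MTCL1, a microtubule crosslinker, by 3.92 ± 0.68. CX3CR1, the fractalkine receptor, rose by 3.27 ± 0.79 and SMPD3 further by 3.03 ± 0.37. DSCAML1, an adhesion molecule, changed by -4.33 ± 0.64, and TP53INP1, a stress-induced gene, by -4.26 ± 0.42. GPR162, an orphan receptor, changed by -4.24 ± 0.83, H2AC6, a histone gene, by -4.14 ± 0.44 and TAMALIN, a scaffold protein, by -4.05 ± 0.81.

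The DNA replication list rose in ISP cells with 12 of 20 members higher, none lower and 8 not past the test (19 adjusted over the list alone; adjusted p = 1.45e-15, adjusted p = 0.159 with an estimated correlation). RRM2, a ribonucleotide reductase subunit, rose from 109 ± 5.18 to 541 ± 31.6 CPM, MCM4, a replicative helicase subunit, from 221 ± 28.8 to 907 ± 120.4 CPM and GINS1 from 26.7 ± 4.12 to 102 ± 16.9 CPM. Mitosis genes rose as a list with 2 of 20 past the test (4 adjusted over the list alone; adjusted p = 2.70e-07, adjusted p = 0.408 with an estimated correlation), AURKA at 1.83 ± 0.52 and PLK1 at 1.58 ± 0.40, both mitotic kinases. The list of the PRC2 complex, which silences genes through histone methylation, rose with 5 of 12 members higher (5 adjusted over the list alone; adjusted p = 7.80e-07). PHF19 changed by 2.08 ± 0.18, EPOP, which limits the activity of the complex, by 1.80 ± 0.41 and EED by 1.18 ± 0.20. Of 12 recombination genes 3 rose (3 adjusted over the list alone) and the list did not pass (adjusted p = 0.0592), although it did without ISP replicate 1 (adjusted p = 0.0172). Those 3 were the DNA repair genes PRKDC (1.33 ± 0.32), XRCC6 (1.13 ± 0.20) and XRCC5 (1.10 ± 0.22), which serve end joining in any cell. Of 18 double-positive stage genes 2 rose, among them AQP3, a glycerol channel (1.33 ± 0.33), and neither that list nor the Notch targets passed (2 and 0 adjusted over the list alone; adjusted p = 0.111 and 0.457). NOTCH1 was at 618 ± 94.4 against 1232 ± 291 CPM and NOTCH3 at 742 ± 1.55 against 1030.1 ± 29.8 CPM. Beside these, B cell markers fell with 2 of 11 members lower (2 adjusted over the list alone; adjusted p = 0.00258, adjusted p = 0.346 with an estimated correlation). Plasmacytoid dendritic cell markers fell as a list of 10 (0 adjusted over the list alone; adjusted p = 0.0350, adjusted p = 0.457 with an estimated correlation), but not with the replicate number as a block (adjusted p = 0.0848) or without CD34+ CD4+ replicate 2 or ISP replicate 2 (adjusted p = 0.661 and 0.137). Thymic epithelium and stroma markers did not pass (adjusted p = 0.149). In all 899 genes rose and 742 fell (1065 and 1331 with DESeq2), 1641 together, against 2934 with the replicate number as a block over the thymus libraries only. The count was 524 and 718 without CD34+ CD4+ replicate 1 and 2, 1091 and 522 without ISP replicate 1 and 2, and 24 named calls held in 10, 13, 16 and 13 cases in the same order.

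On passing from ISP to DP CD3- cells, thymocytes gained CD8 transcripts. CD8B, a coreceptor chain, rose from 38.3 ± 13.7 to 858 ± 244 CPM (4.49 ± 0.77, adjusted p = 0.00112) and CD8A from 112 ± 2.10 to 2252 ± 155 CPM (4.33 ± 1.02, adjusted p = 0.00969). RUNX2, a transcription factor (ENSG00000124813, GRCh38 chromosome 6, 45328157 to 45664349), fell from 55.2 ± 40.6 to 2.22 ± 2.26 CPM (-4.62 ± 0.72, adjusted p = 0.000580). The comparison addressed the entry into the DP stage. ABCG4, a sterol transporter, rose by 7.65 ± 1.36, and KCNA2, a potassium channel, by 6.04 ± 0.64. GJB6, a gap junction protein, rose by 5.77 ± 1.08. UPB1, an enzyme of pyrimidine breakdown, rose by 5.70 ± 0.75 and SSTR3, a somatostatin receptor, by 5.47 ± 0.60. ANXA1, an annexin, changed by -4.36 ± 0.68, and ETV5, an ETS factor, by -4.32 ± 0.39. NDST3, a heparan sulfate enzyme, changed by -4.24 ± 0.43, GPR157, a receptor, by -4.08 ± 0.52 and SLC17A9, a nucleotide transporter, by -3.81 ± 0.48.

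Double-positive stage genes rose as a list with 6 of 18 members higher and 12 not past the test (6 adjusted over the list alone; adjusted p = 4.40e-06, adjusted p = 0.325 with an estimated correlation). ELOVL4, a fatty acid elongase, changed by 3.44 ± 0.75. Notch targets fell with 5 of 11 members lower (5 adjusted over the list alone; adjusted p = 0.0203, adjusted p = 0.0958 with an estimated correlation), including the repressors HES1 (-4.51 ± 0.90) and HES4 (-2.07 ± 0.54) and the Notch regulator DTX1 (-3.82 ± 1.05). DNA replication genes fell with 4 of 20 lower (7 adjusted over the list alone; adjusted p = 4.40e-06, adjusted p = 0.448 with an estimated correlation). UHRF1, a DNA methylation cofactor, changed by -1.50 ± 0.37. The helicase subunits were also lower, MCM6 from 780.3 ± 137 to 314 ± 19.1 CPM and MCM3 from 1173 ± 148 to 476 ± 3.01 CPM. Mitosis genes did not pass (0 adjusted over the list alone; adjusted p = 0.437). MKI67 was at 2190.2 ± 275 against 2287 ± 64.5 CPM and TOP2A at 1133 ± 47.5 against 1206 ± 95.3 CPM. In the BCL2 family 3 of 15 members rose and 2 fell (4 and 3 adjusted over the list alone), and the list did not pass (adjusted p = 0.410). Those that rose were the death-promoting BBC3 (3.80 ± 0.74) and BMF (3.69 ± 0.68) and the protective BCL2L1 (2.31 ± 0.26), whereas the protective BCL2L2 (-1.42 ± 0.25) and the death-promoting BID (-1.05 ± 0.28) fell. Of the recombination list PRKDC fell (-1.24 ± 0.31), and the list did not pass (1 higher and 1 lower adjusted over the list alone; adjusted p = 0.715), with median and mean above and the test below 0. Stress genes rose with 4 of 14 members higher and 1 lower (5 and 1 adjusted over the list alone; adjusted p = 0.0128, adjusted p = 0.336 with an estimated correlation), but not with the replicate number as a block (adjusted p = 0.0508) or without DP CD3- replicate 2 (adjusted p = 0.0734). Altogether 1168 genes rose and 1319 fell, 2487 in total. That count was 1490 and 1583 without DP CD3- replicate 1 and 2 and 1260 without ISP replicate 2. Of 27 named calls, 21 and 22 held without DP CD3- replicate 1 and 2, and 24 and 17 without ISP replicate 1 and 2.

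DP cells with surface CD3 had gained genes induced by TCR signalling as a list (adjusted p = 1.01e-27) relative to DP CD3- cells. EGR3, an early growth response factor (ENSG00000179388, GRCh38 chromosome 8, 22687659 to 22693302), rose from 2.34 ± 1.32 to 39.8 ± 19.4 CPM (4.08 ± 0.65, adjusted p = 0.00486). EGR2 rose from 1.69 ± 1.31 to 32.3 ± 18.0 CPM (4.25 ± 1.04, adjusted p = 0.0477). MYBL2, a cell cycle transcription factor, fell from 196 ± 4.21 to 39.3 ± 14.3 CPM (-2.32 ± 0.56, adjusted p = 0.0452). The comparison addressed positive selection. CCR4, a chemokine receptor, rose by 3.76 ± 0.61, TOX2, an HMG-box factor, by 3.64 ± 0.58, and SIRPG, an adhesion receptor, by 3.18 ± 0.77. LY9, a receptor of the SLAM family, rose by 3.10 ± 0.35 and FRY, a cytoskeletal regulator, by 3.08 ± 0.43. The homologous recombination genes XRCC2 (-2.36 ± 0.53) and BRIP1 (-2.24 ± 0.43), the histone chaperone ASF1B (-2.34 ± 0.53) and the catenin-like CTNNAL1 (-2.27 ± 0.46) fell.

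TCR-induced genes of positive selection rose as a list, with 9 of 19 members higher and 10 not past the test (16 adjusted over the list alone; adjusted p = 1.01e-27). Mitosis genes fell with 1 of 20 lower, PLK1 at -1.93 ± 0.41 (20 adjusted over the list alone; adjusted p = 9.31e-21, adjusted p = 0.108 with an estimated correlation). Thymic maturation and egress genes rose with 1 of 16 higher (5 adjusted over the list alone; adjusted p = 0.000369, adjusted p = 0.0868 with an estimated correlation), namely FOXO1, which drives homing receptor expression (1.86 ± 0.46). Of the alpha beta TCR constant segments TRAC rose (2.02 ± 0.48) and the list of 3 did not pass (1 adjusted over the list alone; adjusted p = 0.134). Double-positive stage genes did not pass (0 adjusted over the list alone; adjusted p = 0.339). RAG1 was at 4464 ± 19.0 against 5526 ± 639 CPM and CD8A at 2121 ± 159 against 2252 ± 155 CPM. The BCL2 family did not pass (0 adjusted over the list alone; adjusted p = 0.852), its median and mean differing in sign, with BMF at 837 ± 148 against 739.9 ± 84.7 CPM and BCL2L1 at 368 ± 13.3 against 502 ± 51.3 CPM. Beside these, B cell markers rose as a list of 11 (0 adjusted over the list alone; adjusted p = 0.00307, adjusted p = 0.346 with an estimated correlation). NK cell markers rose with 1 of 12 members higher (2 adjusted over the list alone; adjusted p = 0.0498, adjusted p = 0.389 with an estimated correlation) and stress genes with 1 of 14 (1 adjusted over the list alone; adjusted p = 0.0224, adjusted p = 0.362 with an estimated correlation). The NK and stress lists did not pass with the replicate number as a block (adjusted p = 0.126 and 0.0512), without DP CD3- replicate 1 (adjusted p = 0.169 and 0.278) or without DP CD3+ replicate 2 (adjusted p = 0.142 and 0.213). A total of 197 genes rose and 207 fell, 404 in all, against 716 with the replicate number as a block (320 higher, 396 lower) and 1021 with the block over the thymus libraries only. The count of 404 was 57 and 250 without DP CD3- replicate 1 and 2, and 40 and 231 without DP CD3+ replicate 1 and 2. A fit of only these 4 libraries gave 0 genes, where edgeR with all libraries had 2855 at an unadjusted p under 0.05 and DESeq2 gave 908, 478 higher and 430 lower. Of 16 named calls 1 and 7 held without DP CD3- replicate 1 and 2, and 2 and 6 without DP CD3+ replicate 1 and 2, and LY9 held in each.

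Mature SP thymocytes, taken as the mean of the CD4+ and CD8+ groups (n = 4), had gained egress (adjusted p = 3.23e-09), MHC class I (adjusted p = 4.55e-18) and interferon-stimulated genes (adjusted p = 3.13e-22) as lists relative to DP CD3+ cells. Double-positive stage genes fell (adjusted p = 1.15e-21). CCR7, the receptor for lymph node chemokines, rose from 59.5 ± 29.5 to 558 ± 96.5 CPM (3.21 ± 0.86, adjusted p = 0.0256). RAG1 (ENSG00000166349, GRCh38 chromosome 11, 36510709 to 36593156), which overlaps RAG2 on the opposite strand, fell from 4464 ± 19.0 to 250.1 ± 294 CPM (-4.20 ± 1.15, adjusted p = 0.0293). The comparison addressed the completion of maturation. GIMAP5, a lymphocyte survival GTPase, rose by 3.90 ± 0.68, RASGRF2, a RAS activator, by 3.63 ± 0.40, and GPR171, a neuropeptide receptor, by 3.60 ± 0.70. DBH, dopamine hydroxylase, rose by 3.54 ± 0.83, CD101, an inhibitory receptor, by 3.48 ± 0.65 and SPON1, an adhesion protein, by 3.40 ± 0.57. COL5A3, a collagen chain, changed by -4.46 ± 0.86 and BMPR1B, a bone morphogenetic protein receptor, by -4.38 ± 0.70.

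Maturation and egress genes rose in SP cells with 11 of 16 members higher, 1 lower and 4 not past the test (11 and 1 adjusted over the list alone; adjusted p = 3.23e-09). KLF2, which induces homing receptors, changed by 3.15 ± 0.76 and FOXO1 by 3.06 ± 0.44, while CD52, a surface glycoprotein, went the other way (-1.54 ± 0.35). Double-positive stage genes fell in 16 of 18 members (17 adjusted over the list alone; adjusted p = 1.15e-21), with the lipid-presenting CD1C at -4.32 ± 0.81 and CD1E at -4.25 ± 0.86. CD4, CD8A and CD8B are on this list and are not independent of the sort. Recombination genes fell in 6 of 12 members (6 adjusted over the list alone; adjusted p = 6.02e-06, adjusted p = 0.102 with an estimated correlation). DNTT changed by -4.12 ± 0.68 and RAG2 by -3.98 ± 0.94. MHC class I genes rose in 7 of 12 members (7 adjusted over the list alone; adjusted p = 4.55e-18). NLRC5, their transactivator, changed by 2.98 ± 0.37, HLA-F by 2.97 ± 0.42 and HLA-B, which has near copies, by 2.81 ± 0.45. Interferon-stimulated genes rose in 13 of 18 members (14 adjusted over the list alone; adjusted p = 3.13e-22), such as the antiviral XAF1 (3.17 ± 0.63), IFI44L (3.16 ± 0.40) and OAS1 (2.93 ± 0.26). TCR-induced genes rose with 4 of 19 members higher (5 adjusted over the list alone; adjusted p = 0.0132, adjusted p = 0.397 with an estimated correlation), including CD27 (2.30 ± 0.37), a costimulatory receptor, but not without DP CD3+ replicate 2 (adjusted p = 0.0639). In the BCL2 family the protective BCL2 (1.43 ± 0.24) and MCL1 (1.13 ± 0.18) rose, the death-promoting HRK (-3.81 ± 0.92) and BMF (-2.92 ± 0.51) and the protective BCL2L1 (-2.51 ± 0.20) fell. The BCL2 family list did not pass (2 and 3 adjusted over the list alone; adjusted p = 0.234). B cell markers fell with 2 of 11 members lower (2 adjusted over the list alone; adjusted p = 0.0125, adjusted p = 0.431 with an estimated correlation) and monocyte and dendritic cell markers with 2 of 13 (2 adjusted over the list alone; adjusted p = 0.0161, adjusted p = 0.382 with an estimated correlation). The latter list did not pass without DP CD3+ replicate 2, SP CD4+ replicate 1 or SP CD8+ replicate 1 (adjusted p = 0.110, 0.0718 and 0.0573). In total 804 genes rose and 1028 fell (1285 and 1240 with DESeq2), 1832 together, against 2888 with the replicate number as a block over the thymus libraries only. The count was 953 and 973 without DP CD3+ replicate 1 and 2. Of 30 named calls 19 and 22 held without them, 28 and 30 without SP CD4+ replicate 1 and 2, and 29 and 30 without SP CD8+ replicate 1 and 2. Replicate 2 of both SP groups held transcripts of the DP stage and of mitosis genes, so the decreases of DP genes are averages over unequal libraries.

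**Figure D4:**
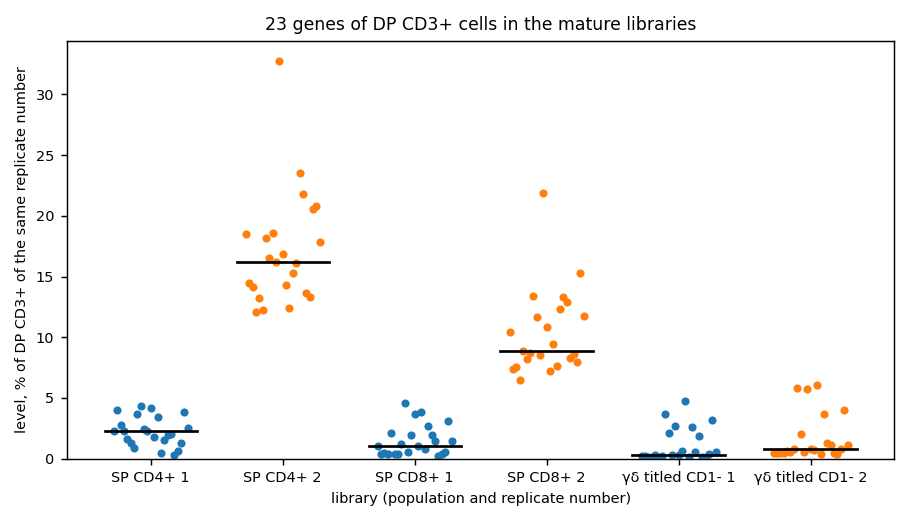
Level of 23 genes as a percentage of the DP CD3+ level of the same replicate number (vertical axis) in the SP and gamma delta libraries titled CD1- (horizontal axis), with a point per gene and the median as a bar. Medians are 16.2% in SP CD4+ replicate 2 and 8.87% in SP CD8+ replicate 2.

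SP CD4+ and SP CD8+ thymocytes differed in the lists of helper (adjusted p = 9.64e-24) and cytotoxic lineage genes (adjusted p = 1.08e-29). The helper list holds CD4 and the cytotoxic list CD8A and CD8B, which are not independent of the sort. ZBTB7B, the transcription factor that fixes the CD4 lineage (ENSG00000160685, GRCh38 chromosome 1, 155002630 to 155018522), was at 239.5 ± 28.8 against 4.46 ± 1.86 CPM (5.75 ± 1.18, adjusted p = 0.0394). CD40LG, a helper ligand, was at 197 ± 2.13 against 5.31 ± 3.70 CPM (5.21 ± 1.06, adjusted p = 0.0367). CCL5, a chemokine of cytotoxic cells, was at 4.45 ± 4.47 against 197 ± 233 CPM (-5.48 ± 1.11, adjusted p = 0.0358). The comparison addressed lineage choice. Higher in SP CD4+ cells were CCR4 (4.33 ± 0.62), SCN3A, a sodium channel (3.96 ± 0.54), ICA1, a membrane traffic protein (3.16 ± 0.54), and ARHGAP31, a regulator of small GTPases (3.05 ± 0.40). Lower were CTSW, a protease of cytotoxic cells (-4.84 ± 0.87) and CDH1, a ligand of an integrin on T cells in epithelia (-3.86 ± 0.80). DAPK2, a kinase (-3.82 ± 0.61), SLC7A3, an amino acid transporter (-3.24 ± 0.45), and FBLN2, a matrix protein (-3.06 ± 0.35), were lower too. The helper lineage list was higher with 5 of 12 members past the test and none lower (9 adjusted over the list alone; adjusted p = 9.64e-24). Regulatory T cell genes were higher with 2 of 12 past the test (6 adjusted over the list alone; adjusted p = 4.77e-08, adjusted p = 0.0950 with an estimated correlation), CCR8 at 4.43 ± 0.77 and FOXP3, the regulatory lineage factor, at 2.05 ± 0.42. The CD8 and cytotoxic list was lower with 4 of 20 past the test (17 adjusted over the list alone; adjusted p = 1.08e-29). The mean log2(CPM + 1) of this list was 5.78 and 4.02 in SP CD8+ and 2.45 and 2.22 in SP CD4+ replicate 1 and 2, so the gap was larger in replicate 1. KLRK1, an activating receptor, changed by -6.92 ± 1.07 and NKG7, a granule protein, by -4.20 ± 0.85. NK cell markers were lower with 1 of 12 past the test (4 adjusted over the list alone; adjusted p = 3.59e-06, adjusted p = 0.0669 with an estimated correlation), XCL1 at -3.71 ± 0.79, whose near copy XCL2 makes the value uncertain. The HOXA list was higher with 3 of 9 members past the test (4 adjusted over the list alone; adjusted p = 2.30e-07). Its mean log2(CPM + 1) was low, at 0.520 and 0.520 in SP CD4+ and 0.193 and 0.262 in SP CD8+ replicate 1 and 2. A total of 86 genes were higher in SP CD4+ and 60 in SP CD8+ cells, 146 in all, against 251 with the replicate number as a block (135 higher, 116 lower) and 469 with the block over the thymus libraries only. That count was 30 and 41 without SP CD4+ replicate 1 and 2, 35 and 55 without SP CD8+ replicate 1 and 2, and 12 without replicate 2 of both, an alternative chosen after seeing the data. Of 17 named calls 4 and 6 held without SP CD4+ replicate 1 and 2, and 3 and 9 without SP CD8+ replicate 1 and 2, and FBLN2 held in each.

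Gamma delta cells titled CD1- had more transcripts of the CD8 and cytotoxic list than those titled CD1+ (adjusted p = 3.40e-17). IL18RAP, a chain of the IL18 receptor (ENSG00000115607, GRCh38 chromosome 2, 102418689 to 102452565), was at 134 ± 128 against 0.686 ± 0.244 CPM (7.60 ± 0.98, adjusted p = 0.000351). CD1A (ENSG00000158477, GRCh38 chromosome 1, 158254137 to 158258269) was at 4.27 ± 3.40 against 491 ± 182 CPM (-6.83 ± 1.27, adjusted p = 0.00423). The comparison addressed the maturation of gamma delta cells. GNLY, a pore-forming granule protein, was higher by 7.54 ± 1.44, GZMK, a granzyme, by 7.26 ± 1.67, and CCL5 by 7.20 ± 1.20. KLRD1, an NK receptor chain, was higher by 7.19 ± 0.98 and NELL2, a secreted signalling protein, by 6.71 ± 1.03. HPGDS, a prostaglandin synthase, changed by -6.23 ± 0.76, and BAHCC1, a chromatin protein, by -6.04 ± 0.82. ETV5 changed by -5.80 ± 0.42, CD1B by -5.93 ± 1.31 and CD1E by -5.75 ± 1.23.

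The CD8 and cytotoxic list was higher in gamma delta cells titled CD1- in 13 of 20 members, with none lower and 7 not past the test (16 adjusted over the list alone; adjusted p = 3.40e-17). FASLG, the death ligand, was at 25.5 ± 29.4 against 0.0652 ± 0.0559 CPM. Innate-like effector genes were higher in 7 of 16 members (11 higher and 1 lower adjusted over the list alone; adjusted p = 1.44e-06, adjusted p = 0.0950 with an estimated correlation). EOMES, an effector transcription factor, changed by 4.78 ± 0.91. MHC class I genes were higher in 9 of 12 (10 adjusted over the list alone; adjusted p = 5.29e-17). HLA-F changed by 3.36 ± 0.46, HLA-B by 2.39 ± 0.47 and HLA-C by 2.25 ± 0.52. Egress genes were higher with 2 of 16 past the test and 1 lower (4 and 1 adjusted over the list alone; adjusted p = 0.00790, adjusted p = 0.182 with an estimated correlation), but not without titled CD1+ replicate 1 (adjusted p = 0.0641). They were IL7R (2.47 ± 0.27) and the complement regulator CD55 (1.51 ± 0.38), with LEF1 the other way (-1.42 ± 0.25). Double-positive stage genes were lower in 9 of 18 members (11 adjusted over the list alone; adjusted p = 5.03e-10, adjusted p = 0.153 with an estimated correlation). The 5 CD1 genes are on this list, were among the lower members and are not independent of the sort by CD1. DNTT and RAG2 are also on the recombination list. Recombination genes were lower in 3 of 12 (4 adjusted over the list alone; adjusted p = 1.36e-06, adjusted p = 0.102 with an estimated correlation), namely DNTT (-5.73 ± 0.98), RAG2 (-4.62 ± 1.32) and ADA (-2.84 ± 0.43). All 20 mitosis genes were lower (20 adjusted over the list alone; adjusted p = 2.35e-27, adjusted p = 0.0822 with an estimated correlation). CCNA2, a cyclin, changed by -3.85 ± 0.66, TOP2A by -3.84 ± 0.83 and BIRC5, survivin, by -3.81 ± 0.85. Gamma delta TCR segments did not pass (0 adjusted over the list alone; adjusted p = 0.489). TRDC was at 1001 ± 159 against 1276 ± 43.2 CPM and TRGC2 at 523 ± 149 against 506 ± 54.2 CPM. NK cell markers were higher in 4 of 12 members (9 adjusted over the list alone; adjusted p = 1.92e-08). In total 564 genes were higher and 820 lower, 1384 together, against 2402 with the replicate number as a block over the thymus libraries only. The count was 571 and 651 without titled CD1- replicate 1 and 2, and 670 and 595 without titled CD1+ replicate 1 and 2. Of 27 named calls 16, 17, 19 and 15 held in the same order.

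Compared with SP cells (n = 4), gamma delta cells of both groups (n = 4) had more transcripts of gamma delta TCR segments and fewer of FOXP3 on average. TRDC was at 1138 ± 185 against 26.7 ± 20.4 CPM (5.67 ± 0.33, adjusted p = 2.16e-07). FOXP3 (ENSG00000049768, GRCh38 chromosome X, 49250436 to 49264826) was at 3.44 ± 2.32 against 58.5 ± 44.7 CPM (-4.04 ± 0.33, adjusted p = 2.41e-06). The comparison addressed the separation of the 2 T cell lineages. MME, a surface peptidase, was higher by 4.33 ± 0.44 and ATP9A, a lipid flippase, by 3.67 ± 0.50. RTKN2, a survival-linked scaffold, was higher by 3.60 ± 0.23, CPNE7, a copine, by 3.52 ± 0.45 and NRROS, a regulator of reactive oxygen species, by 3.51 ± 0.23. NDNF, a secreted factor, changed by -6.72 ± 0.93, and CD101 by -5.88 ± 0.55. TRABD2A, a metalloprotease, changed by -5.87 ± 0.90, CTSL, a cathepsin, by -4.65 ± 0.85 and CTLA4, an inhibitory receptor, by -4.27 ± 0.59.

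All 13 gamma delta TCR segments were higher in gamma delta cells (13 adjusted over the list alone; adjusted p = 2.23e-82). TRDV2 changed by 6.74 ± 0.64 and TRDV3 by 6.10 ± 0.42. Of 3 alpha beta constant segments 2 were lower (2 adjusted over the list alone; adjusted p = 9.75e-05, adjusted p = 0.0711 with an estimated correlation), TRAC at -2.72 ± 0.35 and TRBC2 at -1.15 ± 0.19, and the shared sequence and overlap of these loci leave them uncertain. Innate-like genes were higher in 5 of 16 members and lower in 1 (7 and 2 adjusted over the list alone; adjusted p = 0.0467, adjusted p = 0.479 with an estimated correlation). They included SOX13, a gamma delta lineage factor (4.13 ± 0.96), ZBTB16, the factor of innate-like T cells (3.31 ± 0.78), and KLRB1, a lectin receptor (2.64 ± 0.63), with ID2, an inhibitor of E proteins, lower (-1.64 ± 0.35). The mean log2(CPM + 1) of the innate-like list was 4.38 and 5.77 in gamma delta cells titled CD1-. In those titled CD1+ it was 3.14 and 3.04, within the 2.64 to 3.68 of the SP libraries. That list lost its call with the replicate number as a block (adjusted p = 0.0723) and without SP CD4+ replicate 2, SP CD8+ replicate 2 or titled CD1- replicate 2 (adjusted p = 0.134, 0.112 and 0.302). NK cell markers were higher in 3 of 12 members (3 adjusted over the list alone; adjusted p = 0.0253, adjusted p = 0.346 with an estimated correlation), NCR1 (4.23 ± 1.06), XCL2 (3.39 ± 0.63) and XCL1 (3.06 ± 0.54). The mean log2(CPM + 1) of the NK list was 3.89 and 4.39 in gamma delta cells titled CD1-. In those titled CD1+ it was 1.75 and 1.44, within the 1.31 to 2.72 of the SP libraries. The NK list did not pass without SP CD8+ replicate 2 or titled CD1- replicate 2 (adjusted p = 0.0601 and 0.0797). In the CD8 and cytotoxic list 4 of 20 members were higher and 3 lower (5 and 3 adjusted over the list alone), and the list did not pass (adjusted p = 0.260). It passed without SP CD8+ replicate 1 or titled CD1- replicate 1 (adjusted p = 0.0283 and 0.0490). NKG7 (2.31 ± 0.55), KLRK1 (2.14 ± 0.62) and TBX21, an effector factor (1.81 ± 0.51), were higher, and CD8A (-2.95 ± 0.68), CD8B (-2.68 ± 0.50) and GZMM, a granzyme (-1.70 ± 0.31), lower.

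Double-positive stage genes were lower in gamma delta than in SP cells in 4 of 18 members and higher in 1 (7 and 1 adjusted over the list alone; adjusted p = 0.00300, adjusted p = 0.532 with an estimated correlation). In replicate 1 and 2 the mean log2(CPM + 1) of this list was 4.66 and 6.995 in SP CD4+ and 4.24 and 6.62 in SP CD8+ cells. It was 6.32 and 6.10 in gamma delta cells titled CD1+ and 2.89 and 3.75 in those titled CD1-. In replicate 1 the titled CD1+ library thus lay above both SP libraries. ELOVL4 was lower (-3.00 ± 0.54) and BCL6, a transcriptional repressor, higher (1.71 ± 0.18), and the list did not pass without SP CD4+ replicate 2 or SP CD8+ replicate 2 (adjusted p = 0.129 and 0.322). Mitosis genes were higher as a list with none of 20 past the test (0 adjusted over the list alone; adjusted p = 1.35e-05, adjusted p = 0.482 with an estimated correlation). Their mean log2(CPM + 1) was 6.30 and 6.61 in gamma delta cells titled CD1+, but 2.78 and 3.70 in those titled CD1-, within the 2.74 to 4.78 of the SP libraries. MKI67 was at 342 ± 334 against 121 ± 106 CPM and TOP2A at 221 ± 223 against 64.7 ± 54.1 CPM. Notch targets did not pass (1 higher and 1 lower adjusted over the list alone; adjusted p = 0.908), median and mean differing in sign, with IL7R at 1449.6 ± 1176 against 1989 ± 736 CPM and NOTCH1 at 179.6 ± 33.6 against 183 ± 26.7 CPM. The HOXA list was higher in 5 of 9 members (6 adjusted over the list alone; adjusted p = 1.45e-09). Its mean log2(CPM + 1) was 1.77 and 1.66 in gamma delta cells titled CD1+ and 0.699 and 0.605 in those titled CD1-. The SP libraries ranged from 0.193 to 0.520. A total of 609 genes were higher and 655 lower, 1264 together, against 2075 with the replicate number as a block over the thymus libraries only. Of 32 named calls, 28 and 25 held without SP CD4+ replicate 1 and 2, 30 and 26 without SP CD8+ replicate 1 and 2, 28 and 24 without titled CD1- replicate 1 and 2, and 27 and 26 without titled CD1+ replicate 1 and 2.

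The maturation step of gamma delta cells (titled CD1- against titled CD1+) differed from that of alpha beta cells (SP against DP CD3+) at 401 genes, 179 with a higher and 222 with a lower step in gamma delta cells. MAP7, a microtubule-associated protein (ENSG00000135525, GRCh38 chromosome 6, 136342281 to 136550819), changed by -3.94 ± 0.38 in gamma delta and by 1.12 ± 0.32 in alpha beta cells, a difference of -5.06 ± 0.50 (adjusted p = 0.000154). Its alpha beta rise was from 1.92 to 4.41 CPM (adjusted p = 0.0377). FGR, a SRC family kinase (ENSG00000000938, GRCh38 chromosome 1, 27612064 to 27635277), changed by 2.01 ± 0.57 (adjusted p = 0.0455) and -2.06 ± 0.46, a difference of 4.07 ± 0.75 (adjusted p = 0.0110). PLCG2, a phospholipase of receptor signalling, changed by 1.72 ± 0.41 and -1.99 ± 0.33, a difference of 3.71 ± 0.53 (adjusted p = 0.00278). CDC42EP3, a regulator of the cytoskeleton, changed by 1.38 ± 0.21 and -1.86 ± 0.17, a difference of 3.24 ± 0.27 (adjusted p = 4.71e-05). Egress genes had a lower step in gamma delta cells as a list of 16 with none past the test singly (2 higher and 5 lower adjusted over the list alone; adjusted p = 0.00136, adjusted p = 0.103 with an estimated correlation). Of 18 double-positive stage genes 1 had a higher step and the list did not pass (3 higher adjusted over the list alone; adjusted p = 0.121), median and mean differing in sign. That list passed without titled CD1- replicate 1, SP CD4+ replicate 2 or SP CD8+ replicate 2 (adjusted p = 0.00488, 3.41e-05 and 0.000262). NK cell markers had a higher step in 2 of 12 members (3 adjusted over the list alone; adjusted p = 7.86e-05, adjusted p = 0.0974 with an estimated correlation) and stress genes in 2 of 14 (6 adjusted over the list alone; adjusted p = 4.95e-05, adjusted p = 0.1002 with an estimated correlation). B cell markers had a higher step as a list of 11 (1 adjusted over the list alone; adjusted p = 0.0222, adjusted p = 0.468 with an estimated correlation), but not without titled CD1- replicate 1 or titled CD1+ replicate 2 (adjusted p = 0.331 and 0.112). With the replicate number as a block 828 genes differed, 341 higher and 487 lower, and 1518 with the block over the thymus libraries only. The count of 401 was 137 and 221 without DP CD3+ replicate 1 and 2, 127 and 119 without titled CD1+ replicate 1 and 2, and 181 and 133 without titled CD1- replicate 1 and 2. FGR lost its interaction call without DP CD3+ replicate 1 or either titled CD1+ library. The other 3 genes kept theirs throughout, and calls of single steps are not given.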

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

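The tests of explanations for the double-positive stage, myeloid and CD1 patterns were chosen after the results were seen, and the test of the interaction was fixed beforehand.

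The maturation step differed between gamma delta and alpha beta cells at 401 genes (interaction test). The 4 genes named for opposite steps were MAP7, FGR, PLCG2 and CDC42EP3 (log2 differences -5.06, 4.07, 3.71 and 3.24). In all, 15 genes passed in both steps in opposite directions at the CPM minimum for naming. The steps differ in more than lineage, because the alpha beta step starts from DP cells and the gamma delta step from cells divided by CD1.

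Double-positive stage transcripts were present in replicate 2 of both SP groups, which enter the alpha beta step, beside mitosis genes (mean log2(CPM + 1) of 4.70 and 4.78 in replicate 2 of SP CD4+ and SP CD8+, 2.88 and 2.74 in replicate 1). Of 23 genes chosen from replicate 1 alone (at least 100 CPM in DP CD3+ and at most 5% of that in SP libraries), the median share of the DP CD3+ replicate 2 level was 16.2% in SP CD4+ replicate 2 and 8.87% in SP CD8+ replicate 2. The third quartile was 1.34 and 1.49 times the first, so these genes lay near a common share, as cells or RNA of the DP stage could produce, while the mitosis genes lay at a larger share of DP CD3+ replicate 2 (6.22) and below DP CD3- replicate 2 (7.91). A difference of all replicate 2 libraries of mature cells stays open, since the test had 1 other such library, gamma delta cells titled CD1-, with 0.753% in replicate 2 and 0.277% in replicate 1. DP cells, carried-over RNA and less mature SP cells, as a subset or throughout, stay open, since interferon-stimulated genes were lower in replicate 2 (median log2 ratio -0.44 in SP CD4+ and -0.546 in SP CD8+) while the egress list went both ways (0.20 and -0.18). MHC class I genes were lower by less (-0.189 and -0.289). CD8A and CD8B in SP CD4+ replicate 2 exceeded replicate 1 by 12.6% and 11.4% of the DP CD3+ replicate 2 level. For CD4 in SP CD8+ replicate 2 the excess was 9.81%.

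Myeloid transcripts rose from CD34+ CD1+ to CD34+ CD4+ cells, mostly in replicate 2. The median log2 ratio of replicate 2 to replicate 1 was 1.38 over 12 markers without CD1C, which thymocytes also express, with quartiles of 0.67 and 2.25 and 11 of 12 higher, which is consistent with unequal amounts of myeloid cells or their RNA. A change of the thymocytes equal in both libraries is argued against by these ratios, beside which the double-positive stage genes had a median of -0.16. Replicate 2 was also higher in plasmacytoid dendritic cell (4.09 against 2.79), B cell (2.71 against 1.89) and granule markers (2.74 against 1.25), as means of log2(CPM + 1), so the pattern was not limited to monocytes. A difference between donors stays open and untested, and the sort label of this population names no myeloid exclusion.

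The CD1 sign of the gamma delta groups differs between titles and sort phenotype entries. The median log2 fold change of 5 CD1 genes, titled CD1- against titled CD1+, was -5.75, which argues against titles exchanged between the groups. All 5 CD1 genes were lower in both titled CD1- libraries, as exchanged sort phenotype entries could produce. The transcripts measure mRNA and not the surface protein that was sorted, and no biological explanation was tested.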

How the results depend on the processing

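The alternatives without HPC, with a block over the thymus libraries only, and without replicate 2 of both SP groups were chosen after the results were seen. The alternatives that left out a library in turn assume that the lone sample of a group varies like the other groups, and the cause of the differences below was not tested unless stated.

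No named gene changed sign between the main test and an alternative, counting only genes that passed in either. Of 212 named gene calls all held with RLE scaling and with the replicate block, 210 with DESeq2, 169 with only the groups compared and 168 without the low-count filter, where more genes were tested. Of the named genes not past the main test, 3 passed with DESeq2 and 1 with only the groups compared. With the block over the thymus libraries only, 1 passed. Of 1060 pairs of a named call and a left-out library 764 held, and 58 of 83 held without replicate 2 of both SP groups. RLE scaling moved no count of genes by more than 1.5 times, and it moved the share of increases in no comparison by over 10 percentage points. The direction with more genes turned for CD34+ CD1- cells against HPC (from 56.6% to 48.8% higher), ISP against CD34+ CD4+ cells (from 54.8% to 49.8%) and DP CD3+ against DP CD3- cells (from 48.8% to 50.6%). It turned with DESeq2 for the same 3 comparisons (2880 higher and 3184 lower, 1065 and 1331, and 478 and 430) and for SP against DP CD3+ cells (1285 and 1240), and with the replicate block for ISP cells (1115 and 1133). Of 154 sort marker levels, 125 moved by less than 1 SD with plain CPM and 29 by more. The comparison of sort marker levels with the deposited normalized counts, chosen before the data were examined, was not run.

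Without the low-count filter, 2 genes changed between CD34+ CD1+ and CD34+ CD1- cells and 31 between CD34+ CD4+ and CD34+ CD1+ cells. With DESeq2 these counts were 67 and 120, and 908 genes changed between DP CD3+ and DP CD3- cells, 472 between SP groups, 2085 between gamma delta groups and 1108 in the interaction. Without a fold change threshold, which admits smaller changes by construction, 2564 genes changed from CD34+ CD4+ to ISP cells and 1923 between gamma delta and SP cells. With only the groups compared, which leaves fewer samples to estimate the spread, 1304 genes changed from HPC to CD34+ CD1- cells, 3 from CD34+ CD1+ to CD34+ CD4+ cells, 0 between the DP groups (edgeR, 2855 at an unadjusted p under 0.05 with all libraries and 908 with DESeq2) and 6 between the SP groups.

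With the replicate number as a block over all libraries, 28 genes changed from CD34+ CD1+ to CD34+ CD4+ cells, 716 between DP groups, 251 between SP groups and 828 in the interaction. The block ended 13 of 151 list calls, among them innate-like genes in gamma delta against SP cells (adjusted p = 0.0723), while monocyte and dendritic cell markers gained a call as lower in gamma delta against SP cells (adjusted p = 0.0499, 0.0535 without the block). It changed no call of a named gene and moved no other count by more than 1.5 times. With the block over the thymus libraries only, the counts were 14 for CD34+ CD1+ against CD34+ CD1- cells, 72 for CD34+ CD4+ cells, 2934 for ISP, 1021 for DP CD3+, 2888 for SP against DP CD3+, 469 for SP CD4+ against SP CD8+, 2402 for the gamma delta groups, 2075 for gamma delta against SP cells and 1518 for the interaction.

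Without HPC, 1 gene changed from CD34+ CD1- to CD34+ CD1+ cells, 18 to CD34+ CD4+ cells, 672 between DP groups, 263 between SP groups and 866 in the interaction. The HPC replicates agreed least (correlation of log2 CPM of 0.915, against 0.934 to 0.973 in the other groups). Without replicate 2 of both SP groups 12 genes differed between the SP groups. With the correlation between genes estimated, 36 of 151 list calls held.

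With a library left out in turn, the counts ranged from 3487 to 7328 for CD34+ CD1- against HPC, 0 to 16 for CD34+ CD1+ against CD34+ CD1- and 0 to 6 for CD34+ CD4+ against CD34+ CD1+ cells. The edgeR count of 0 with all libraries in the middle case went with 871 genes at an unadjusted p under 0.05 and 67 with DESeq2. Further ranges were 522 to 1091 for ISP, 1260 to 1783 for DP CD3-, 40 to 250 for DP CD3+ and 953 to 1724 for SP against DP CD3+ cells. They were 30 to 55 for SP CD4+ against SP CD8+, 571 to 670 for the gamma delta groups, 863 to 1303 for gamma delta against SP cells and 119 to 447 for the interaction. Genes varying across populations ranged from 8085 to 10313 and list calls from 144 to 170. For the list gamma delta TCR segments, CD34+ CD1+ against CD34+ CD1-, the adjusted p was 0.0250 as higher with all libraries, and adjusted p = 0.481 with an estimated correlation. With a library left out it ranged from 2.99e-05 (without CD34+ CD1- replicate 1) to 0.655 (without CD34+ CD1- replicate 2), where the direction reversed, and without CD34+ CD1+ replicate 1 it was 0.307.

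Depth limits the rarest transcripts, since a count of 0 over a group of 2 libraries allows up to 3 counts. In simulated data edgeR called 13 of 100 genes changed 2-fold and 78 of 100 changed 4-fold.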

Other observations

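The test of other splits in this part was chosen after the result was seen.

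Gamma delta against SP cells was the comparison with at least 3 libraries on each side. The replicate numbers were taken to pair these samples, although the labels name no donor. The real grouping was therefore set against the 18 of 35 splits with 2 libraries of each number on each side. These are too few for a share under 0.05. In a fit of the 8 libraries 1 of the 18, the real one, gave 595 genes, and the highest other gave 36. The 17 splits that divided the numbers unequally gave up to 209 genes, with replicate 1 set against replicate 2. With the replicate number as a block over all libraries this comparison gave 1627 genes.

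Immediate-early and stress genes were high in HPC, with FOS at 1381 and 724 CPM and DUSP1 at 650.2 and 629.9 CPM in replicate 1 and 2. As a list they fell in CD34+ CD1- cells, 9 of 14 lower and 2 higher (9 and 2 adjusted over the list alone, adjusted p = 7.79e-11, and adjusted p = 0.0181 with an estimated correlation). They were higher in gamma delta cells titled CD1- than in those titled CD1+, in 5 of 14 members (5 adjusted over the list alone, adjusted p = 2.20e-07, and adjusted p = 0.0516 with an estimated correlation).

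HOXA9 was at 13.5 and 11.4 CPM in gamma delta cells titled CD1+, against 1.51 and 1.40 CPM in those titled CD1-. The HOXA list was lower in the latter in 5 of 9 members (6 adjusted over the list alone, adjusted p = 9.92e-07, and adjusted p = 0.00685 with an estimated correlation).

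PRC2 genes were lower in gamma delta cells titled CD1- in 4 of 12 members (4 adjusted over the list alone, adjusted p = 5.48e-05, and adjusted p = 0.0210 with an estimated correlation), and JARID2, a cofactor of the complex, was at 543 and 464 CPM in those titled CD1+.

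Gamma delta TCR segments were transcribed in the early thymic groups. From HPC to CD34+ CD1- cells 12 of 13 rose (12 adjusted over the list alone, adjusted p = 3.72e-22, and adjusted p = 0.0163 with an estimated correlation). From ISP to DP CD3- cells 7 of 13 fell (7 adjusted over the list alone, adjusted p = 3.10e-06, and adjusted p = 0.129 with an estimated correlation).

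KRT8, a keratin gene chosen after its values were seen, was at 22.8 and 0.315 CPM in SP CD8+ replicate 1 and 2 and at 18.7 and 0.896 CPM in CD34+ CD1+ replicate 1 and 2. The mean log2(CPM + 1) of the thymic epithelium and stroma list was higher in replicate 1 than in replicate 2 in every thymus group. It was 1.63 and 0.402 in SP CD8+ cells, for example, against 1.59 and 1.65 in HPC.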
